A study of Arabidopsis thaliana with 12 samples.

How the data were processed

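Total RNA of Arabidopsis thaliana, ecotype Columbia 0, was measured by array; the tissue and the array type are not given in the sources used here. The 12 samples are 6 of wild type (WT_dark) and 6 of the prors2 mutant (prors2_dark), all from plants kept dark overnight, per the labels. The labels describe the mutant as lacking prolyl-tRNA synthetase. Groups and sample numbers were taken from the sample titles. The wild-type titles read WT2, a 2 whose meaning is not given in the sources used here. A second label, the source of the material, reads wild type for all 12 samples, those titled prors2 included, so the grouping rests on the titles alone.

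The values used are the deposited intensities of 3439 probes in 12 samples, on a linear scale in arbitrary units. How the authors obtained these intensities (background subtraction, scaling, spot averaging) is not given in the sources used here. Values run from exactly 0 to a ceiling shared by all samples, so both ends of the deposited scale are limited. The distributions were not equal between samples, so the deposited intensities had not been quantile-normalized. Whether the scale of different samples is comparable as deposited stays unknown. The number of arrays limits the precision.

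Of the 3439 probes, 692 list 1 gene in the platform annotation, 870 list several and 1877 are not listed there. The gene table of assembly TAIR10.1 matched 690 of the 692, and it was used for names and for which genes neighbour each other. No gene was named from a probe with several genes. No probe lists PRORS1 (AT5G52520), a gene for prolyl-tRNA synthetase. It was taken as the mutated gene from the description of the mutant, which is an assumption. The label of the mutant samples could therefore not be checked on that gene.

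Values at 0 were treated as missing, the others were taken to log2 and quantile-normalized between samples, and probes of the same gene were averaged. Of 3438 resulting features, the 2684 with at least 3 values above 0 in each group were tested, 530 of them with 1 named gene, and 754 were not tested. Differences (prors2 minus wild type) were tested, 2-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over 6 against 6 samples, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. Adjusted p-values in the text are from limma unless another test is named. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry. Differences of single summary values between the groups were tested by 2-sided exact permutation.

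The tests, the rule for named genes, 23 gene lists and the first set of alternatives were fixed before the data were examined. The rule names PRORS1, the 12 genes with the largest difference upward and the 12 downward among those past the threshold, and up to 4 members of each list with the smallest adjusted p. The lists hold 369 loci, of which 15 have a probe of their own and 11 were tested. They belong to 7 lists: Calvin cycle, light-harvesting proteins, photosystem I subunits, photosystem II subunits, plastid ribosomal proteins, plastid fatty acid synthesis and tetrapyrrole synthesis. The other 16 lists had no tested member. Among these, the lists of aminoacyl-tRNA synthetases and of other ribosomal proteins were planned from gene descriptions. They were searched for in gene symbols and synonyms only and came out with 0 genes. Whether the array holds such genes was therefore not examined. Another 4 lists (subunits and factors of the chloroplast NDH complex, assembly factors of the photosystems and the cytochrome complex, GH9 endoglucanases, MADS-box factors) were written after the probes' gene names and some values had been seen.

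Samples with consecutive numbers (1 and 2, 3 and 4, 5 and 6) resembled each other more than other samples of their group did, by a wide margin in prors2 and a small one in wild type. Nothing in the labels says whether they are separate plants, repeat hybridisations or repeat readings. The p-values therefore measure only the spread between these samples, which may be technical, and those over 6 against 6 samples are too small if consecutive samples share an RNA. Counts with each pair averaged (3 against 3) are given beside them. This alternative was added after the values had been seen.

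The fit was tested on simulated data with the spread of the real features and changes of 1.5-fold, 2-fold and 4-fold. These were given to 60, 70 and 70 of the 2684 features. A first version of this test asked for more 2-fold changes to be recovered than the noise of these arrays permits, and the 4-fold class was added for that reason. With independent samples, 6 against 6 recovered 35.7% of the 2-fold and 77.1% of the 4-fold changes, and 2.41% of the calls were false. With the within-pair correlation of the real data (0.728 over both groups, 0.522 in wild type and 0.862 in prors2), 6 against 6 recovered 87.1% of the 4-fold changes. However, 41.1% of the calls were false. With pairs averaged, 56.7% of the 4-fold and 3.28% of the 2-fold changes were recovered, and 5.26% of the calls were false. The shares of false calls hold for this small number of changed features and cannot be carried over to the real calls.

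Alternatives were the values as deposited (log2 only), median centring, centring on features outside the photosynthesis and plastid ribosomal lists, removal of the dimmest 25% of features, a pseudocount of 0.0192 with zeros kept, eBayes with trend and robust settings, the sample number as a block, and leaving out each sample. Added later were pairs averaged, pairs as a random block, the set of consecutive numbers as a fixed block, features above 0 in all 12 samples, and leaving out each set of consecutive numbers.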

Results

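Transcript levels were measured by array in 6 wild-type samples and 6 samples of prors2, an Arabidopsis mutant described as lacking prolyl-tRNA synthetase, the enzyme that charges tRNA with proline for protein synthesis. All plants had been kept dark overnight. Signal differed between the groups over the whole array. The median deposited intensity was 0.0764 ± 0.0103 (SD, n = 6) in wild type and 0.333 ± 0.0724 (SD, n = 6) in prors2, and the number of the 3439 probes listed at 0 was 821 ± 79.8 (SD, n = 6) and 507 ± 80.3 (SD, n = 6). The brightest probes went the other way, with a 99th percentile of 13.2 ± 1.41 (SD, n = 6) in wild type and 11.1 ± 1.26 (SD, n = 6) in prors2. The exact permutation p was 0.00216 for medians and zeros, the smallest that 6 against 6 samples can give, and 0.0238 for the 99th percentile. Among probes above 0, the SD of log2 intensity was 2.49 in wild type and 1.71 in prors2 (exact permutation p = 0.00216), so the mutant arrays spanned a narrower range. The summed intensity was 2801 ± 200 in wild type and 3195 ± 304 in prors2 (SD, n = 6 each; exact permutation p = 0.0303). These permutation tests treated the 12 samples as independent. Their p-values are too small if consecutive samples share an RNA, and none was run with pairs averaged.

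**Figure D1:**
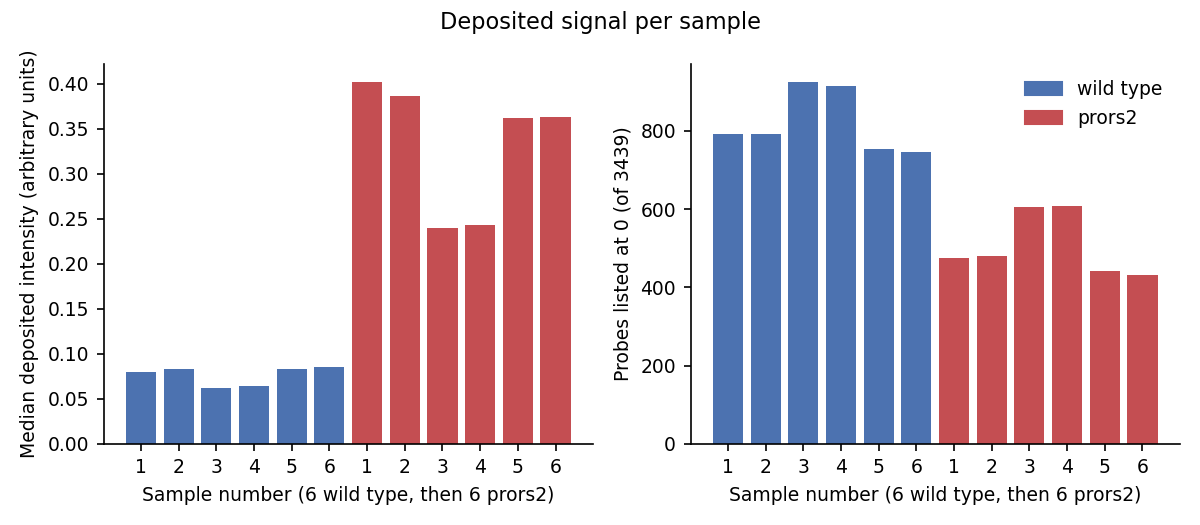
Median deposited intensity in arbitrary units (left) and number of probes listed at 0 (right) for each of the 12 samples, wild type in blue and prors2 in red, 1 bar per sample. The wild-type counts of zeros lie between 746 and 926 and the prors2 counts between 431 and 609, with no overlap.

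The comparison of prors2 with wild type asks which transcripts differ in dark-adapted plants when this enzyme is affected. Relative to the whole signal distribution, 167 of the 530 features with 1 named gene rose in prors2 and 90 fell. The 12 named genes that rose most had mean deposited intensities of 0.0918 or less in wild type. All but AT2G46300 lay below the wild-type median of 0.0764. Those that fell most had mean deposited intensities of 0.411 or less in both groups. The 5 tested photosynthesis genes, which were bright, did not pass the main test, after quantile normalization of all features. PSBY and LHB1B2 passed in some other settings, such as normalization of only the features above 0 in all 12 samples. With each sample centred on its median all 5 were lower and passed. Over all 2684 tested features, 671 rose and 554 fell (limma, adjusted p under 0.05). Among these calls, 441 rises and 472 falls were of features above 0 in all 12 samples. With each pair of consecutive samples averaged, 307 rose and 208 fell among 2459 features, and 81 rose and 35 fell among 486 named genes.

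Among the genes that rose, AT3G53470 had a deposited intensity of 0.00571 ± 0.00491 (SD, n = 6) in wild type and 0.495 ± 0.180 (SD, n = 6) in prors2. Its log2 difference after normalization was 3.82 with a standard error of 0.31 (limma, adjusted p = 8.6e-06). This rests on 4 wild-type values above 0. Since wild-type samples 3 and 4 were at 0, AT3G53470 had no test with pairs averaged. AT5G63490 had the highest log2 difference of the 12 named by the rule, 5.49 with a standard error of 1.49 (adjusted p = 0.0119), but 3.30 without wild-type sample 6, and it did not pass with pairs averaged (adjusted p = 0.0743). Leaving out 1 wild-type sample also lowered SWAP70 to 2.38 (without sample 2), AT2G33180 to 2.55 (without sample 5), AT4G08630 to 2.47 (without sample 6), AT2G19870 to 3.44 (without sample 1) and AT2G25640 to 2.83 (without sample 3), each still past the threshold. AT2G19870 rose by 4.40 on the log2 scale and AT3G44810, which encodes an F-box protein, by 3.68. AT3G44810 had 3 wild-type values above 0 and no test with pairs averaged. SWAP70 (AT2G30880) rose by 3.40, from an intensity of 0.0269 ± 0.0243 to 0.520 ± 0.190 (SD, n = 6 each). AT3G13180, of the NOL1/NOP2/sun family of RNA methyltransferases, rose by 3.26, and AT2G46300, a late embryogenesis abundant hydroxyproline-rich family protein, by 3.12. The others were AT2G25640 (3.61), AT2G33180 (3.60), AT4G39570 (3.49), AT4G08630 (3.41) and AT4G13680 (3.29). Of these 12 genes, 9 had at least 1 wild-type value at 0, which was left out of the normalized wild-type mean and so raises that mean. For AT2G46300 it was the other way. It had 6 wild-type but 5 prors2 values above 0. Leaving out prors2 sample 3, which was at 0, raises its prors2 mean and so its difference. With zeros kept and a pseudocount, the differences of the 12 genes were smaller, from 1.55 for AT2G46300 to 3.25 for AT5G63490. AT2G46300 did not pass in that setting (limma, adjusted p = 0.230). All 12 passed before any normalization, with differences from 4.33 to 7.07. On that scale 1869 of the 2684 tested features passed as higher and the median difference was 1.49, so this is no separate support. With pairs as a random block, 7 of the 12 did not pass: AT2G19870, AT2G25640, AT2G33180, AT4G39570, AT4G08630, SWAP70 and AT2G46300 (limma, adjusted p from 0.0551 to 0.240).

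The genes that fell had lower normalized values in prors2, and their differences were smaller as deposited. AT1G67820, a protein phosphatase of the PP2C family, had an intensity of 0.371 ± 0.0478 (SD, n = 6) in wild type and 0.224 ± 0.0478 (SD, n = 6) in prors2, and its normalized log2 difference was -2.20 with a standard error of 0.17 (limma, adjusted p = 2.0e-06). AT4G27390 had the lowest difference, -3.09, with intensities of 0.106 ± 0.0169 and 0.0609 ± 0.0476 (SD, n = 6 each). AT5G52530, the gene directly beside PRORS1 in the TAIR10.1 annotation, had intensities of 0.117 ± 0.0292 and 0.0972 ± 0.0227 (SD, n = 6 each) and a normalized log2 difference of -2.38 with a standard error of 0.21 (limma, adjusted p = 7.4e-06). THIC (AT2G29630), which makes the pyrimidine part of thiamine, had a difference of -2.30, with intensities of 0.411 ± 0.0313 and 0.274 ± 0.160 (SD, n = 6 each). TPP2 (AT4G20850), tripeptidyl peptidase II, had a difference of -2.14, and AT3G27110, a peptidase of the M48 family, of -2.21. AT5G05400, a leucine-rich repeat protein of the disease resistance type, had a difference of -1.91, and AT1G34270, of the exostosin family, of -2.36. The others were AT1G06510 (-2.60), AT1G51080 (-2.44), AT1G21350 (-1.99) and AT4G00170 (-1.97). AT4G27390 and TPP2 were among the dimmest 25% of features and have no value once these are removed. With pairs as a random block TPP2 and AT1G21350 did not pass (limma, adjusted p = 0.134 and 0.0606). TPP2 also did not pass with median centring (0.0607) and had no test with pairs averaged. As deposited, with no normalization, the median difference over all features was 1.49. On that scale 2 of these 12 genes kept an adjusted p under the threshold, 8 were lower without passing, and TPP2 (0.57) and AT1G21350 (0.16) were higher in prors2.

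**Figure D2:**
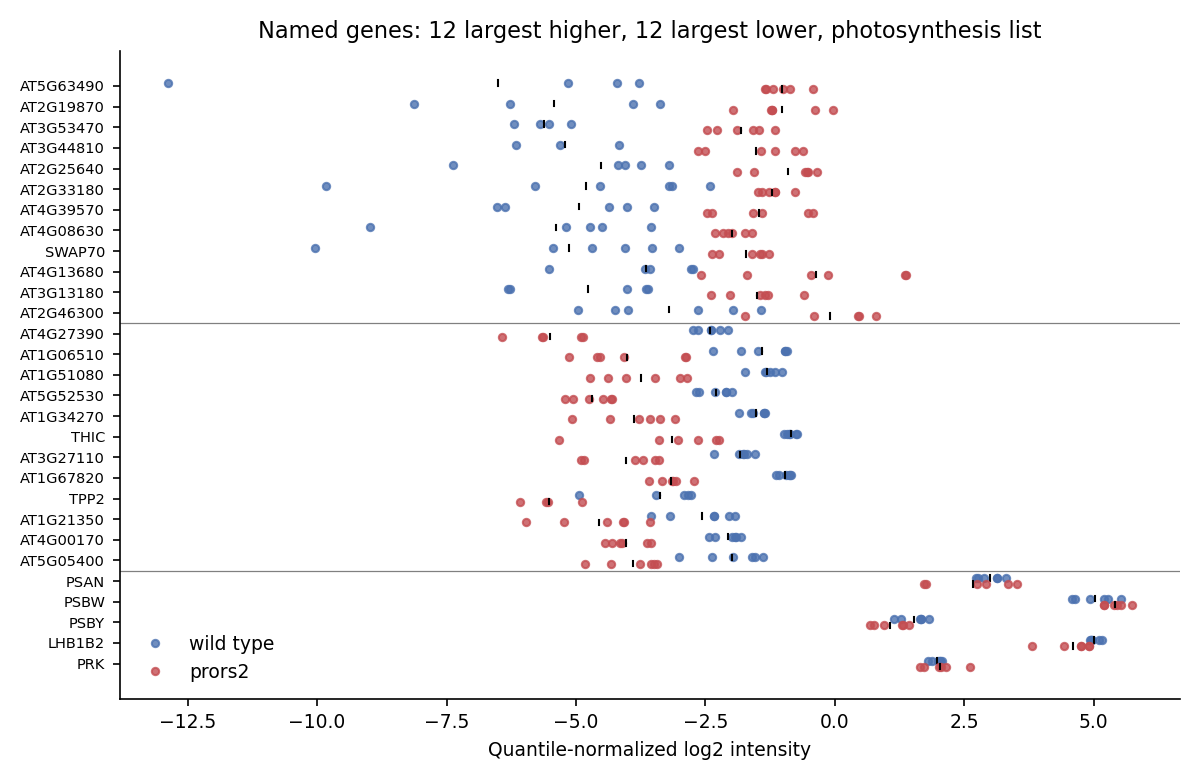
Quantile-normalized log2 intensity (horizontal axis) of the 12 named genes with the largest rise, the 12 with the largest fall and the 5 tested photosynthesis genes, 1 point per sample with a value above 0 (wild type blue, prors2 red), and a black tick at each group's mean. Groups lie apart for the first 24 genes except AT2G46300 and TPP2, and they overlap for the photosynthesis genes except LHB1B2.

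Among the lists fixed in advance, 5 photosynthesis genes were tested, and none passed after quantile normalization with all features. LHB1B2 (AT2G34420, also called LHCB1.5), a light-harvesting protein of photosystem II, had intensities of 38.0 ± 2.74 in wild type and 20.6 ± 5.21 in prors2 (SD, n = 6 each) and a log2 difference of -0.42 (limma, adjusted p = 0.101). The photosystem I subunit PSAN had intensities of 9.23 ± 1.67 and 6.35 ± 3.07 and a log2 difference of -0.33 (SD, n = 6 each; limma, adjusted p = 0.413). The photosystem II subunits PSBY and PSBW had differences of -0.46 (adjusted p = 0.0660) and 0.39 (adjusted p = 0.118). PRK, the phosphoribulokinase of the Calvin cycle, had a difference of 0.06 (adjusted p = 0.801). The mean over the 5 genes was -0.15 and the median -0.33 (camera p = 0.602, and p = 0.666 with an estimated correlation; fry p = 0.185; adjusted over the 2 fixed lists large enough to test, 0.602, 0.666 and 0.185). None passed when adjusted over the list alone (0 of 5). With quantile normalization over only the features above 0 in all 12 samples, PSBY (-0.63, limma, adjusted p = 0.00919) and LHB1B2 (-0.57, adjusted p = 0.0247) passed, and with a pseudocount and zeros kept they did too (-0.64, adjusted p = 0.00853, and -0.57, adjusted p = 0.0259). PSBY also passed with trend and robust settings (adjusted p = 0.0333), without wild-type sample 4 (0.0421), without prors2 sample 4 (0.0462) and without numbers 3 and 4 (0.0121), but neither gene passed with pairs averaged (0.322 for PSBY and 0.363 for LHB1B2). PSBW passed as higher with the set of consecutive numbers as a fixed block (adjusted p = 0.0340), but not with pairs averaged (0.392). With median centring PSBW passed as lower (adjusted p = 9.9e-06). Within the sets of consecutive numbers the mean was -0.13 for samples 1 and 2, -0.45 for 3 and 4, and 0.14 for 5 and 6.

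The mean of the photosynthesis list depended on the scaling. The mean over the 5 genes was -0.49 as deposited and -2.08 with each sample centred on its median. Limma's camera, adjusted over the 2 fixed lists, gave an adjusted p = 7.5e-04 on the first of these scales and an adjusted p = 1.7e-05 on the second. Under median centring the brightest features as a class were lower in prors2, with a median log2 difference of -1.18, and the dimmest were higher, with 0.47. With median centring all 5 genes passed as lower: LHB1B2 (-2.51, limma, adjusted p = 1.3e-07), PRK (-1.85, adjusted p = 1.4e-06), PSBW (-1.67, adjusted p = 9.9e-06), PSAN (-2.27, adjusted p = 1.3e-05) and PSBY (-2.10, adjusted p = 1.3e-05). As deposited, LHB1B2 (-0.92, adjusted p = 7.96e-04) and PSBY (-0.52, adjusted p = 0.0367) passed as lower, and PSAN (-0.68), PRK (-0.26) and PSBW (-0.089) were below 0 without passing. The direction of PSBW and PRK therefore turned with the scale.

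Of the plastid ribosomal protein genes, 3 were tested and 1 fell relative to the other probes. AT4G01310 (RPL5) had a log2 difference of -0.56 with a standard error of 0.18 (limma, adjusted p = 0.0248), but its deposited intensity was higher in prors2, 0.379 ± 0.0527 against 0.199 ± 0.0463 (SD, n = 6 each), and passed as higher on that scale (0.94, adjusted p = 4.7e-04). It did not pass with pairs averaged (adjusted p = 0.214), nor without numbers 1 and 2 or numbers 3 and 4. AT3G54210 (RPL17) had a difference of -0.52 (adjusted p = 0.135, but 0.0203 without numbers 3 and 4) and AT5G65220 (RPL29) of 0.34 (adjusted p = 0.184, but 0.0360 with the set as a fixed block). Neither AT3G54210 nor AT5G65220 passed with pairs averaged (limma, adjusted p = 0.381 and 0.477). With median centring all 3 were lower and passed, AT4G01310 at -0.64 (limma, adjusted p = 0.0121), AT3G54210 at -1.39 (adjusted p = 4.7e-04) and AT5G65220 at -1.31 (adjusted p = 7.1e-05), so the direction of AT5G65220 turned. The mean was -0.25 and the median -0.52 (camera p = 0.542, and p = 0.583 with an estimated correlation; fry p = 0.0743; adjusted, 0.602, 0.666 and 0.149), and 1 gene passed when adjusted over the list alone. Within the sets of consecutive numbers the mean was -0.68, -0.0014 and -0.055.

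In tetrapyrrole synthesis, the pathway to chlorophyll and haem, AT1G74470 (CHLP), the geranylgeranyl reductase, had a difference of -0.39 (adjusted p = 0.0968, but 0.0187 over features above 0 in all 12 samples and 0.0131 with the pseudocount) and CHLM, the Mg-protoporphyrin methyltransferase, of 0.04 (adjusted p = 0.923). AT1G74470 also passed as lower as deposited (-0.58, limma, adjusted p = 0.0121) and with median centring (-2.16, adjusted p = 2.0e-07), and CHLM passed as higher as deposited (1.38, adjusted p = 0.00153). In plastid fatty acid synthesis, FATB, an acyl-ACP thioesterase, fell by 1.62 on the log2 scale (limma, adjusted p = 0.00351), with deposited intensities of 0.146 ± 0.0781 in wild type and 0.160 ± 0.0371 in prors2 (SD, n = 6 each). FATB did not pass with pairs averaged (adjusted p = 0.0550) or without numbers 1 and 2 (adjusted p = 0.0610). PRORS1 has no value here, since no probe lists it.

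The share of changed features that were higher depended on the scale. It was 54.8% after quantile normalization, 41.9% with median centring (653 higher, 905 lower) and 92.8% as deposited (1869 higher, 144 lower). After quantile normalization it also depended on values at 0. Among changed features at 0 in at least 1 sample 73.7% were higher (230 of 312). Among those above 0 in all 12 samples 48.3% were higher (441 of 913). With zeros kept and a pseudocount the share was 48.4%. Among named genes 65.0% of the changed features were higher, against 52.1% of the other changed features (Fisher's exact test, 2-sided, p = 2.4e-04). That p treats features as independent, although all come from the same 12 samples, and features with values at 0 were not set apart. Within single sets of 2 against 2 samples, whose error is only that between consecutive samples and may be technical, limma called 538 higher and 599 lower for samples 1 and 2, 463 and 418 for 3 and 4, and 542 and 517 for 5 and 6.

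**Figure D3:**
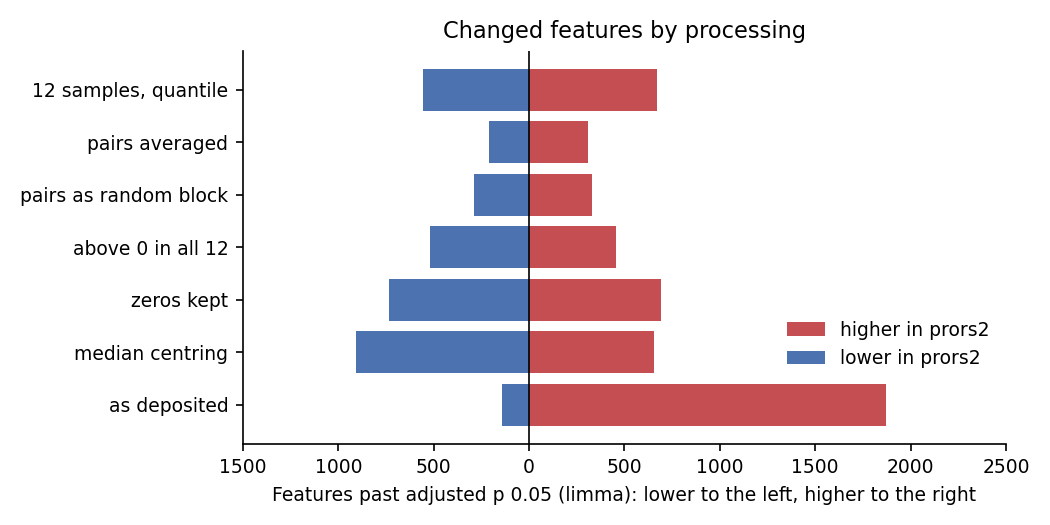
Number of features past an adjusted p of 0.05 (limma), higher in prors2 to the right in red and lower to the left in blue, for 7 ways of processing the values. Averaging pairs gives 307 and 208, and the values as deposited give 1869 and 144.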

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

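All tests of explanations in this part except the comparison with lists of like brightness were chosen, or their bounds written, after the result was seen; that comparison was itself added after the list's result was known.

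Of 65 groups of 6 values examined for a sample far from the others, 2 had one, where chance gives about 1 in 20. Wild-type sample 2 had a normalized log2 intensity of -10.05 for SWAP70, and the other wild-type samples lay between -5.44 and -3.00. The prors2 sample 3 had -5.32 for THIC, and the others lay between -3.39 and -2.23. Groups of a gene with a value at 0 were not examined, which left out 9 of the 12 rising genes in wild type. Far values occurred there too. For example, wild-type sample 6 had -12.88 for AT5G63490, and the others with a value lay between -5.15 and -3.78. The rate of such samples is therefore not known for the genes with zeros. Features outside the comparison also differed: 51 were listed at 0 in all wild-type samples and above 0 in all prors2 samples, and 1 was the other way round. Of the 51, 10 have 1 named gene, among them AT3G11150 (mean 0.865 in prors2), AT2G14660 (0.810) and GH9B16 (0.482), chosen for their high values.

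The first pattern is the large number of changed features. Of 100 splits of the 12 samples into 6 and 6, 1 gave as many as 1225, the real one, and the highest other split gave 1, which excludes chance only if the 12 samples are independent, and nearly all of these splits break up the similar pairs. With pairs averaged the real split gave 515 and the highest other 0, but 1 of 10 splits is the least that this design can give. Counting both samples of a pair as independent is not the whole cause, since those 515 features passed with pairs averaged. A monotone difference in scale is removed by quantile normalization, apart from the values at 0. After it 45.6% of features were still called, and 50.2% of the 1940 features above 0 in all 12 samples when normalized among themselves. Whether added background on the mutant arrays is the whole cause cannot be told. With pairs averaged, 14.8% of the brightest and 17.6% of the dimmest features were called. The prors2 median intensity of 0.333 lay above the wild-type upper quartile of 0.258, so the brightest features may not be free of background. A difference in labelling or hybridisation between the groups that acts differently on different probes may remain, and nothing in the labels separates it from an effect of the mutation, which stays open and untested.

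The second pattern is the lower level of the photosynthesis genes under median centring. The mean over the 5 genes, with features above 0 in all 12 samples, was -1.86, and 16.3% of 10000 random lists of like brightness had a mean as low, against 0.02% of lists drawn without regard to brightness. This is consistent with the narrower signal range of the mutant arrays as a source of the shift. A real fall of bright transcripts, photosynthesis genes included, would narrow the range too and stays open.

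The third pattern is AT5G52530, which lies beside PRORS1 with 0 genes between them and ranks 4 from the lowest of 530 named genes. It was lower in all 26 alternatives and past the threshold in 25; the exception was the values as deposited, with -0.26 (limma, adjusted p = 0.293), on a scale where the median feature was at 1.49, so an effect of the normalization cannot be ruled out. Within 200 genes on each side of PRORS1, 4 of 10 tested genes had changed, 2 of them lower, against 253 of 520 elsewhere (Fisher's exact test, p = 0.753), and 10 genes are too few to decide on a changed chromosome segment. AT5G52530, which raised the question, was itself counted among the 10 tested, the 4 changed and the 2 lower genes. If PRORS1 is the mutated gene, an effect of the mutation or an insertion there on its neighbour may be a further explanation, which was not tested.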

How the results depend on the processing

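The pair, set and zero-value alternatives below were added after the data were seen; the planned value of PRORS1 and its permutation test were not run, since no probe lists it. Quantile normalization as an alternative did not apply, since it is the main setting. All 12 genes named as rising were higher under every alternative that gave a value, but not all passed: 7 lost their call with pairs as a random block, AT5G63490 with pairs averaged, AT2G46300 with the pseudocount (adjusted p = 0.230, limma), AT2G33180 and SWAP70 without numbers 3 and 4, and AT4G13680 without numbers 5 and 6. Of the 12 that fell, TPP2 and AT1G21350 lost theirs with pairs as a random block and TPP2 with both centrings. Counts as deposited were 2013 changed, 1869 higher and 144 lower; median centring gave 905 lower and centring outside the lists 909. Pairs averaged gave 515, 307 and 208, and pairs as a random block 621, 330 and 291. Without numbers 5 and 6, 444 were higher. The other alternatives gave between 849 and 1558 changed features. Leaving out each sample gave 1122 to 1195 changed, 604 to 653 higher and 506 to 542 lower, photosynthesis means of -0.22 to -0.087 and ribosomal means of -0.31 to -0.17. The labels do not say that the numbers pair the groups; residuals of same-numbered samples correlated weakly, at 0.059 to 0.178, and 8 of 12 samples correlated best with their own number, a hint from the data only. With the number as a block, 1209 features changed (669 higher, 540 lower), the photosynthesis mean stayed at -0.15 and the ribosomal mean at -0.25. The photosynthesis mean passed the test as deposited (-0.49), with median centring (-2.08) and with centring outside the lists (-2.09), and was 0.0021 without numbers 3 and 4. The ribosomal mean was 0.47 as deposited and 0.079 with the pseudocount. The photosynthesis shift with median centring was tested against lists of like brightness; for the other changes the cause was not tested, apart from fewer samples where pairs were averaged or sets left out.

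Single genes turned direction as follows. As deposited: TPP2 0.57, AT1G21350 0.16, PRK -0.26, PSBW -0.089, FATB 0.34, AT4G01310 0.94, AT3G54210 0.20, CRR21 0.88, LPA19 0.91, ATAB2 1.80, GH9B8 2.46, GH9B12 1.24, AT2G35490 0.13, AT2G04700 0.14 and CCS 0.19. Median centring: PRK -1.85, PSBW -1.67, AT5G65220 -1.31, CHLM -0.20, NdhS -1.38, PSB27 -1.07, ATAB2 0.21, GH9B8 0.84 and AGL26 -0.032. Centring outside the lists: PRK -1.85, PSBW -1.68, AT5G65220 -1.32, CHLM -0.21, NdhS -1.39, PSB27 -1.08, ATAB2 0.20, GH9B8 0.83 and AGL26 -0.040. Pseudocount: PRK -0.13, CHLM -0.15 and AGL26 -0.010. GH9B8 was 0.50 with the number as a block, 0.36 with pairs averaged, 0.25 with pairs as a random block, 0.29 with the set as a fixed block and 0.30 without numbers 1 and 2. PRK was -0.093 over features above 0 in all 12 samples and -0.14 without numbers 5 and 6. CHLM was -0.051 without numbers 1 and 2 and -0.11 without 5 and 6, PSB27 was -0.15 without 1 and 2, and PSAN 0.20 without 3 and 4. Leaving out each sample gave PRK -0.054 to 0.14, CHLM -0.072 to 0.26 and GH9B8 -0.97 to 0.65. AT4G01310 lost its call in 3 of these 12 runs, without wild-type sample 2 or 4 or prors2 sample 1. The cause was not tested.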

Other observations

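The tests in this part were chosen after the values had been seen, and so were the genes named in it.

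Of the 530 named genes tested, 48.5% changed, so the genes below are single examples, not a tested group. AT2G32040, a folate transporter of the plastid envelope, rose by 2.96 on the log2 scale (limma, adjusted p = 1.2e-04). CCB3, an assembly factor of the cytochrome b6f complex, rose by 2.76 (adjusted p = 5.1e-04), and PIFI, a factor linked to the chloroplast NDH complex, rose by 1.44 (adjusted p = 1.5e-04). The wild-type intensity of CCB3 was 0.00590 ± 0.00746 (SD, n = 6), with 4 wild-type values above 0. With zeros kept and a pseudocount, the difference of CCB3 was 1.43 (limma, adjusted p = 0.00724). AT2G35490, a fibrillin, had a difference of -1.79, AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, of -1.45, AT3G58610, the ketol-acid reductoisomerase of branched-chain amino acid synthesis, of -1.40, and AT1G54500, a rubredoxin, of -1.28 (adjusted p from 3.5e-05 to 4.4e-04 for these 4 genes). CCS, the copper chaperone of superoxide dismutase, had a difference of -1.70 (adjusted p = 5.6e-04). These falls hold relative to the other probes: as deposited, AT2G35490 (0.13), AT2G04700 (0.14) and CCS (0.19) were higher in prors2 and AT3G58610 was at -0.010, none of them past the threshold.

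Of the lists written after the data were seen, the NDH list had PIFI past the threshold and NdhS (0.49) and CRR21 (-0.36) not. Limma's fry gave p = 1.4e-04 and camera p = 0.363 (p = 0.367 with an estimated correlation). Fry tests the members alone, took the 12 samples as independent and was not run with pairs averaged. Since 48.5% of all named genes changed, the fry result is no support for a change particular to this list. The assembly list had CCB3 past it and PSB27 (0.30), LPA19 (-0.81, limma, adjusted p = 0.0503) and ATAB2 (-0.18) not; adjusted over the list alone 2 passed. LPA19 passed with the pseudocount (0.0110), the number as a block (0.0211), the set as a fixed block (0.00752), without the dimmest 25% of features (0.0427), without numbers 1 and 2 (0.0181), and without prors2 sample 1 (0.0175), prors2 sample 2 (0.0350) or wild-type sample 4 (0.0319), but not with pairs averaged (0.208), and it was higher as deposited. GH9B12 passed as lower with the set as a fixed block (0.0182), but not with pairs averaged (0.388). Of the GH9 endoglucanases GH9B11 rose (3.10), with GH9B12 at -0.51 and GH9B8 at -0.18 not passing. GH9B11 had 5 wild-type values above 0, and its difference was 1.82 with zeros kept and a pseudocount. Within the sets of consecutive numbers it was 1.06, 3.96 and 5.07. Of 2 genes listed as MADS-box factors, AGL103 rose (1.18) and AGL26 (AT5G26880, 0.19) did not pass. The list was too short to test. Calls of these members depended on the scale: as deposited GH9B12 (1.24, limma, adjusted p = 2.6e-04), GH9B8 (2.46, 0.0420), CRR21 (0.88, 5.4e-04), ATAB2 (1.80, 1.1e-04) and AGL26 (1.55, 1.9e-05) passed as higher, and with median centring NdhS (-1.38, 7.1e-04), PSB27 (-1.07, 0.0102) and CRR21 (-0.70, 0.0141) passed as lower. In other settings 2 members of these lists gained a call with the number as a block, LPA19 among them, and 2 without numbers 3 and 4. Adjusted over the lists large enough to test, limma's camera gave 0.738 for the NDH, assembly and GH9 lists alike, and fry gave 2.9e-04 for the NDH list.

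In all 12 samples the most similar sample of the same group was the one with the neighbouring number. Over 1940 features above 0 in all samples, such pairs correlated at 0.918 to 0.940 in wild type and 0.960 to 0.984 in prors2 (across features, which are not independent replicates), other pairs of the same group at 0.877 to 0.916 and 0.854 to 0.912, and samples of different groups at 0.736 to 0.808. Consecutive numbers may be repeat measurements of the same RNA or the same filter, but these 12 of 12 samples are the observation that raised the question, and nothing further tested it. Whether the sets were also shared between the groups cannot be told apart from chance: of the 6 orders in which the mutant sets can be matched to the wild-type sets, 1, the given one, had a mean residual correlation as high as 0.0894 (highest other 0.0380), and 6 orders are too few. The set of samples 3 and 4 had the most probes listed at 0 in both groups.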
